A study of Mus musculus with 4 samples.

How the data were processed

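Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts adapters into open DNA, in mouse T-helper 17 cells of strain C57BL/6NJ. The labels give 4 biological replicates of 1 cell type, all with the same donor identifier, and no other group. The 4 peak lists, 1 per replicate, were the measurement used here; aligned reads were not used here. Per the labels the lists refer to the mm10 genome build. The deposited peak names carry words for masked, deduplicated and sorted reads, 72hrs, ASTARR.insert, and a library tag, KS134 in replicates 1 and 2 and KS136 in replicates 3 and 4; what the tags, the 72hrs and ASTARR.insert stand for is not explained, and the assay is ATAC-seq as the labels give it. The aligner, the peak caller and their versions are not given in the sources used here.

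Each line of a deposited list holds a region, a summit position as an offset in bp from the region's start, and 4 values made by the authors' peak caller. The deposited signal value is the enrichment of the peak over background and is not normalised between replicates. The deposited -log10 p and -log10 q values are per peak, and the lowest -log10 q was 1.00 ± 0.003 (SD, n = 4), so each list stops at about that value. The deposited display score follows the -log10 q, up to a limit of 1000, and was not used here. The lists hold no read counts, so sequencing depth is unknown and no counting intervals are given; precision is the spread between the 4 replicates. Signal was used to rank or compare regions within a replicate; where a mean and SD over replicates are given, they are of the deposited values as they stand.

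Regions on chromosomes 1 to 19, X and Y were kept. Overlapping regions of the 4 lists (at least 1 bp) were merged into a union, and a union region with a region from all 4 replicates is called shared. Chance overlap was measured on 20 seeded shuffles of each list within its chromosomes. Similarity of replicates was the Jaccard index of covered bases and Spearman's rho of signal across regions found in both members of a pair; regions are not independent replicates, so no p is given. Annotation came from GENCODE release M21 on GRCm38.p6, with 21851 protein-coding genes. A summit within 1 kb of an annotated transcription start site (TSS) was a promoter summit, and the others were called distal and, for the genome classes, divided into exon, intron and intergenic.

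18 gene lists were fixed before the data were examined, as were the motif strings, the tests, most of the other settings and the rule for naming genes. They cover Th17, Th1, Th2, regulatory T (Treg) and follicular helper T (Tfh) programmes, naive or memory T cells, T-cell identity and receptor, activation, polarising cytokine input, CD8 or NK, B cell, myeloid, erythroid or megakaryocyte, neuron, hepatocyte, epithelium, muscle and housekeeping genes. Of 238 listed genes 237 were matched by symbol to the annotation; Clec7a of the myeloid list was not. A promoter was open when each of the 4 replicates had a region of its own within 1 kb of a TSS. This share was compared with 10000 random lists of the same size, matched on the ratio of observed to expected CpG at the promoter in 5 bins. Region density was the mean of log2(1 + shared regions) over the gene body and 10 kb on each side, compared with 10000 random lists matched on gene length in 10 bins. Both permutation tests were two-sided, with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. The smallest p that 10000 random lists can give is 2.0e-04. The Th17 list was compared with each of 4 other helper lists by a two-sided permutation test of length-adjusted density (100000 resamples), adjusted over the 4.

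Promoter openness was first computed from the merged shared regions. It was changed to the planned measure, each replicate's own regions, after those first values had been seen, and the merged reading was kept as an alternative. The change ended 1 call, a lower share of open promoters in the neuron list, whose adjusted permutation p is 0.0486 with merged regions and 0.0508 with each replicate's own regions; the range over its alternatives is 0.0144 to 0.754.

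For 19 consensus strings, the share of summits with a match on either strand within 50 bp was divided by the mean share in windows of the same size centred 200 bp on each side. The same ratio for the reversed, not complemented, string served as background. A motif was counted when its lowest ratio over the replicates was above 1 and above the highest reversed ratio, with both defined in every replicate. With 4 replicates no sign-flip test can pass the threshold, so none was used.

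Named genes are every member of the Th17 list, the members of the other helper lists with the most and fewest shared regions, other list members as examples, the 10 genes outside the lists with the most shared regions, the genes nearest to the 10 distal and 10 promoter regions with the best mean signal rank, and those nearest to the strongest regions found in 1 replicate alone. Some of the genes this rule names are counted in their groups but not reported here by name. Genes with closed promoters, the STAT split by tag, and the Y-linked genes and Il2ra regions in the closing section were singled out after their values were seen.

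The tests were tested on simulated data. All calls on simulated data used an unadjusted p under 0.05. With 200 simulated lists of 14 genes, random lists were called denser in 2.5% and less dense in 2% of cases, lists raised 1.5-fold in 79% and lists raised 2-fold in 99.5%. Their region counts were drawn from a Poisson distribution whose mean depended on gene length alone. Further variation between genes was not simulated, so these rates may be too high for the real lists. For promoter openness, 0.5% of random lists were called higher and 98% of lists raised by 50 points. These lists were drawn from the bins poorest in promoter CpG. The rate does not hold for lists whose random lists are mostly open, where such a rise is not possible. For a difference between 2 lists, with none planted 3% were called one way and 4% the other, and 54% were called at a log2 difference of 0.5 and 100% at 1. The AP-1 string planted at the centre of random sequences was found in 100% of them.

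Alternatives were stricter -log10 q limits of 5 and 10, the strongest 50000 regions of each replicate, other overlap rules, regions in at least 3 or at least 2 replicates, leaving out each replicate, other promoter windows, gene windows and nearest-TSS assignment, lists without matching, other motif windows and other ranks of strong regions. Regions on unplaced sequences and the mitochondrial genome were left out of the comparisons, and ambiguous gene symbols were left out of the ranked genes. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and BLAST+ 2.17.0.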

Results

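Open chromatin was profiled by ATAC-seq in primary mouse T-helper 17 (Th17) cells, the CD4 T cells that secrete interleukin 17. The series holds 1 group of 4 biological replicates, so the comparisons below are between regions, genes and sequences within these cells. Each replicate had 84615 ± 697 open regions (SD, n = 4) on chromosomes 1 to 19, X and Y, with a median width of 639.5 ± 21.1 bp. They covered 64.5 ± 2.11 Mb, or 2.44% ± 0.080 of the genome. Sequencing depth is unknown because the peak lists hold no counts, so no intervals are given.

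The first comparison asked how far the replicates found the same regions. The 4 lists merged into 101015 regions, of which 68696 (68.0%) were present in all 4 replicates. With summits required within 100 bp the share was 54.5%, and with a -log10 q of at least 10 it was 76.4%. Shuffled lists shared at most 70 regions. Of a single replicate's regions, 82.8% ± 0.952 (SD, n = 4) lay in the shared set and 4.45% ± 0.499 were found in that replicate alone. The shared regions had a median signal of 7.20 ± 0.173 and those of 1 replicate alone 2.80 ± 0.087. Jaccard indices of covered bases ranged from 0.757 to 0.779 over the 6 pairs, and Spearman's rho of signal across regions averaged 0.958. Replicates with the same library tag in their peak names were more alike, with a mean Jaccard index of 0.777 against 0.761 between tags. The strongest regions confined to 1 replicate's list lay nearest to Fcgr3, which encodes an Fc receptor of myeloid and NK cells, and Fam50b in replicate 2, U2surp in replicate 3, and Dlg2 in replicate 4. Even the first of these ranked only 25105th within its replicate.

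Open regions were concentrated at promoters. Summits within 1 kb of a TSS made up 15.8% ± 0.095 (SD, n = 4) of each list, 7.21 ± 0.046 times the share in shuffled lists. Exons held 3.59% ± 0.045 (1.41 ± 0.018 times the shuffled share), introns 44.6% ± 0.223 (1.19 ± 0.006) and intergenic sequence 36.0% ± 0.189 (0.623 ± 0.003). Every difference from the shuffled share was larger than the spread between replicates. The promoters of 13591 of 21851 protein-coding genes (62.2%) were open in all 4 replicates, from 8.72% in the group of genes poorest in promoter CpG to 96.4% in the richest. With a promoter window of 500 bp the promoter fold was 12.3.

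The next comparison asked which gene programmes had open promoters. In the Th17 list 14 of 15 promoters were open in all 4 replicates, among them the cytokine genes Il17a, Il17f and Il21 and the receptor genes Il23r and Ccr6. The exception was Il22, the interleukin 22 gene, with no promoter region in any replicate. Random lists matched on CpG had a median of 40% open against 93.3% here (adjusted permutation p = 7.2e-04, from the smallest p the random lists can give).

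Promoters of the other helper programmes were also open in these cells. In the Th1 list 13 of 14 were open, including Tbx21, the Th1 master regulator, whereas the promoter of Ifng, the interferon gamma gene, was open in 3 of 4 replicates. In the Treg list 12 of 14 were open, with Foxp3, the Treg master regulator, open in 1 replicate and the integrin gene Itgae in 0. At Foxp3 and Ifng a shared region, centred 1448 and 1663 bp from the nearest TSS, reached the promoter window once merged. Their counts of replicates therefore depend on how far each replicate's own region extends. All 11 Tfh promoters were open, including Bcl6, the Tfh regulator, and Cxcr5. All 15 genes of T-cell identity and receptor, such as Cd3e, Cd4 and Zap70, were open against a random median of 26.7%. These 4 lists also had an adjusted permutation p of 7.2e-04, and the naive or memory list (11 of 12 open) had 0.0468. The Th2 list, with 11 of 15 open, did not pass (adjusted permutation p = 0.0652). It passed with a -log10 q of at least 10 (0.0365) and with regions in at least 2 replicates (0.0252), within a permutation range of 0.0252 to 0.595 over its alternatives. Its closed promoters were those of Il4 (open in 2 replicates), Il13 (1), Il1rl1 (0) and Ptgdr2 (0), while Gata3, the Th2 regulator, was open in all 4.

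No list of another cell type passed the test as more open than its random lists. Open promoters numbered 4 of 12 in the CD8 or NK list, 3 of 12 in the B cell list, 3 of 13 in the myeloid list and 5 of 11 in the erythroid or megakaryocyte list. The B cell gene Ms4a1 had no shared region at all. For tissues outside blood, 8 of 15 neuron, 1 of 14 hepatocyte, 6 of 12 epithelium and 1 of 11 muscle promoters were open. The muscle list was the only one to pass the test as lower than its random lists (9.09% against a median of 36.4%, adjusted permutation p = 0.0264), with Mylpf as its open gene; the neuron list did not pass (0.0508). The adjusted permutation p was 0.401 for the activation list (14 of 14 open), 0.0652 for polarising cytokine input (12 of 12) and 0.619 for housekeeping genes (15 of 15), whose random lists were also mostly open. It ranged from 0.401 to 1 for the CD8 or NK, B cell, myeloid, erythroid, hepatocyte and epithelium lists. In all, 6 of 18 lists were higher than random lists and 1 was lower.

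Within the strongest 50000 regions of each replicate only the Tfh and T-cell identity lists remained higher, the Th1, Treg, naive or memory and muscle lists no longer passed, and the neuron and epithelium lists passed as lower. There the adjusted permutation p of the Th17 list was 0.0750 (range over its alternatives 7.2e-04 to 0.0750). With a -log10 q of at least 10, by contrast, 8 lists were higher: the Th2 list and polarising cytokine input (adjusted permutation p = 0.0368; range over its alternatives 0.0198 to 1) came to pass. The neuron list passed as lower under 7 of its 13 alternatives, within an adjusted permutation p range of 0.0144 to 0.754. These were a -log10 q of at least 10 (0.0368), the strongest 50000 regions (0.0144), a promoter window of 500 bp (0.0180), merged shared regions (0.0486), and leaving out replicate 1 (0.0459), 2 (0.0450) or 4 (0.0481).

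**Figure D1:**
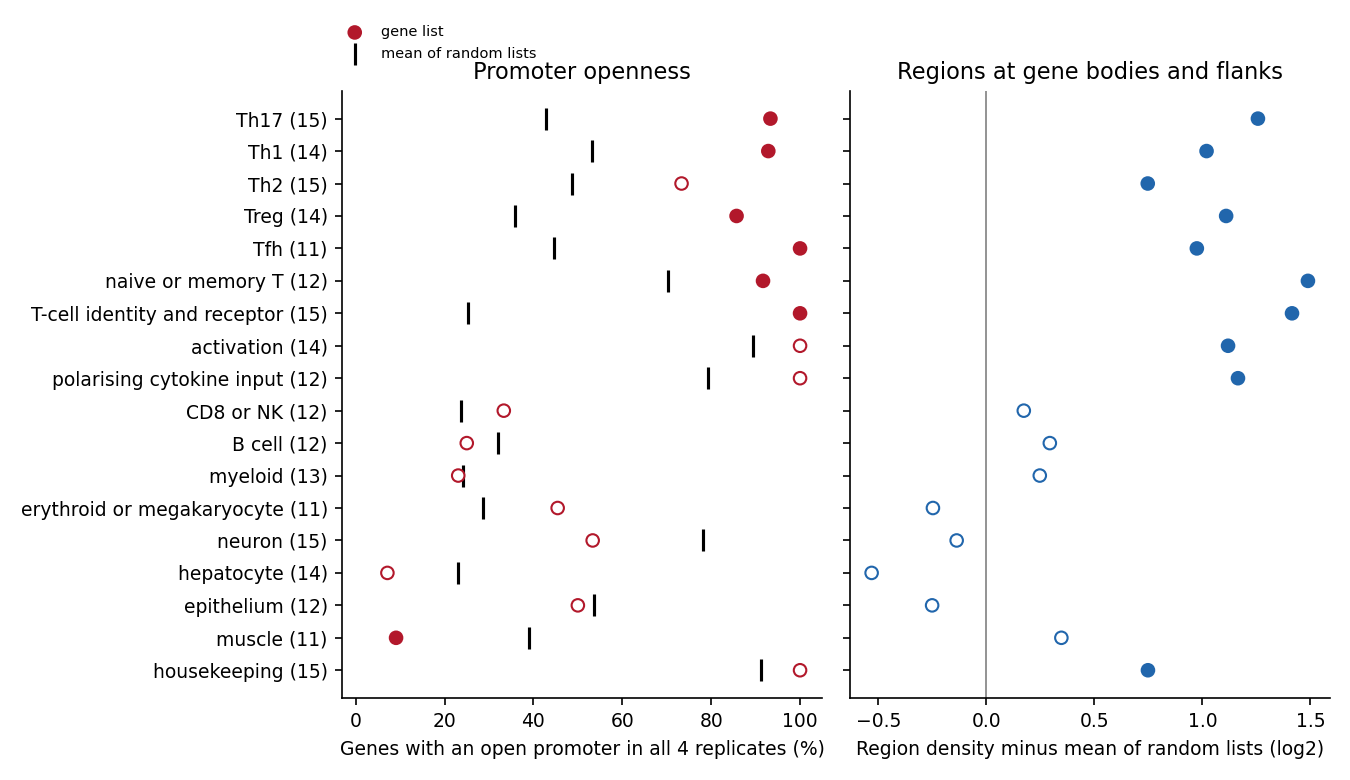
Left, percent of each list's genes with an open promoter in all 4 replicates (circles) and the mean of matched random lists (bars); right, region density of each list minus the mean of random lists (log2), with the number of genes in brackets and no error bars. Filled circles had an adjusted p under 0.05 and open circles did not. The Th17 list lies at 93.3% and 1.26 (both filled) and the hepatocyte list at 7.14% and -0.53 (both open).

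Loci of the T-cell programmes also held more shared regions than other genes of like length. The excess in mean log2(1 + regions) was 1.26 for the Th17 list, a 2.39-fold difference in 1 + regions rather than in the number of regions. It was 1.02 for Th1, 0.75 for Th2, 1.11 for Treg, 0.97 for Tfh, 1.49 for naive or memory T cells and 1.42 for T-cell identity and receptor genes. Activation genes had an excess of 1.12 and polarising cytokine input genes of 1.16. Housekeeping genes also passed, with 0.75. The adjusted permutation p of these 10 lists ranged from 5.1e-04 to 0.0025. None of the other 8 lists passed: the excess was 0.17 for CD8 or NK, 0.29 for B cell, 0.25 for myeloid, -0.25 for erythroid or megakaryocyte, -0.14 for neuron, -0.53 for hepatocyte, -0.25 for epithelium and 0.35 for muscle (adjusted permutation p from 0.0654 to 0.625). With distal regions only, an alternative added after seeing the data, the housekeeping call ended (0.43, adjusted permutation p = 0.0714; range over its alternatives 4.5e-04 to 0.159) and the muscle list passed (0.64, adjusted permutation p = 0.0158; range 0.0158 to 0.918). Within the strongest 50000 regions the Th1, Tfh and polarising cytokine input lists no longer passed. The hepatocyte list passed as less dense with a -log10 q of at least 10 (-0.54, adjusted permutation p = 0.0416) and without matching (0.0312), within a range of 0.0312 to 0.417 over its alternatives.

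Among Th17 genes, Rora, which encodes a nuclear receptor of the ROR family, had the most shared regions, 56 over its 734461 bp. Il23r, the interleukin 23 receptor gene, had 13, Stat3, the transcription factor gene downstream of interleukins 6 and 23, had 11, and Il1r1, an interleukin 1 receptor gene, had 10. Irf4 had 8, Il21 had 7, Il17f and Batf 6 each, Il17a, Ccr6 and Ahr 5 each, the chemokine gene Ccl20 4, Maf 3 and Il22 1. Within the strongest 50000 regions Rora had 28, Il23r and Il1r1 7 each, Stat3 6, Irf4 and Batf 4 each and Ccr6 3; Il17a, Il17f and Ccl20 had 2 each, Il21, Ahr and Maf 1 each and Il22 0. With regions assigned to the nearest TSS, Maf had 54 and Ahr 36. The strongest region at Il17a lay upstream, at -5433 bp from its TSS, on chromosome 1 from 20724452 to 20726492, at percentile 81.6 ± 0.763 (SD, n = 4) of signal among shared regions. The promoter region of Il17a was at percentile 9.11 ± 2.64 (SD, n = 4). The strongest region at Il23r, on chromosome 6 from 67458892 to 67459900, was at percentile 98.8 ± 0.852, and that at Stat3 at 95.6 ± 0.694.

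**Figure D2:**
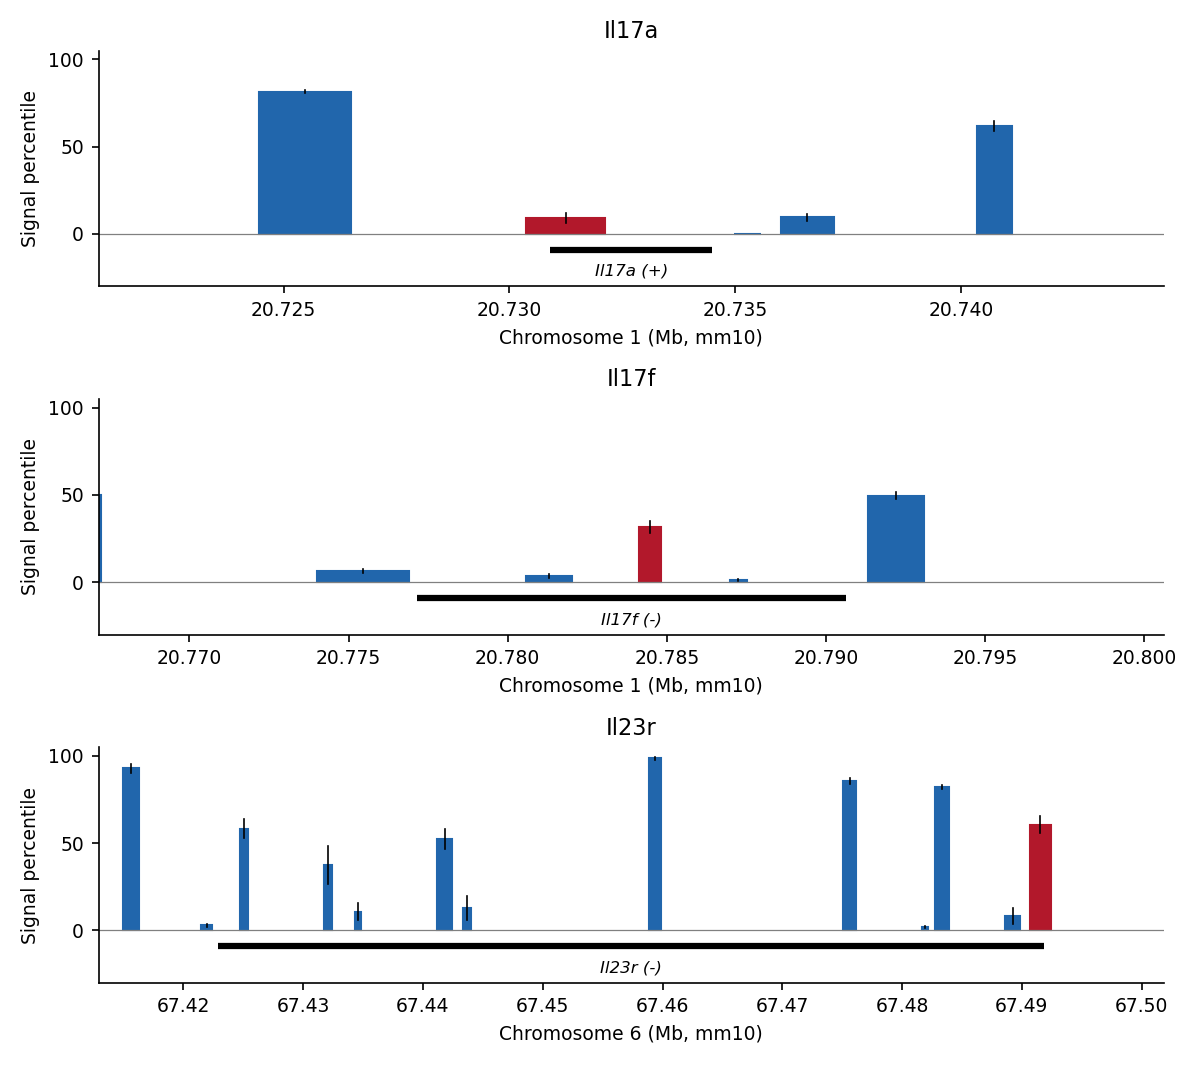
Shared regions at Il17a, Il17f and Il23r, drawn to scale along the chromosome in Mb (mm10); height is the mean signal percentile among shared regions with error bars of 1 SD over 4 replicates, promoter regions are red and others blue, and black bars are gene bodies. The tallest region at Il17a lies upstream at percentile 81.6, and its promoter region at 9.11.

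The Th17 list was then set against the other helper programmes, to ask whether the cells' own programme was the most densely open. Length-adjusted density in the Th17 list exceeded that of Th1 by 0.24, of Th2 by 0.52, of Treg by 0.15 and of Tfh by 0.28 on the log2 scale. By permutation test 0 of 4 differences passed after adjustment and 1, against Th2, had an unadjusted p under 0.05 (p = 0.0230, adjusted 0.0921); the adjusted p of the others ranged from 0.442 to 0.551. In the Th1 list Stat4 had the most shared regions (14) and Ifng the fewest (2). In the Th2 list Il4ra had 7 and Areg 1. Il2ra, the interleukin 2 receptor alpha gene, had 19 in the Treg list, where Tnfrsf18, Il10 and Tigit had 3 each. Cxcr5 had 10 and Ascl2 2 in the Tfh list. The Th2 difference passed without replicate 1 (0.57, adjusted permutation p = 0.0433) and without replicate 4 (0.56, 0.0490), and also with regions in at least 3 replicates (0.63, 0.0194), in at least 2 (0.60, 0.0374) or without length matching (0.76, 0.0355). Over all its alternatives the adjusted permutation p ranged from 0.0194 to 0.697.

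Outside the lists, the most shared regions fell in very long gene models: Gm20388 (320 regions over 4435 kb) and Fgfr2, a growth factor receptor gene (120 over 2961 kb). These annotated models enclose 71 and 29 other protein-coding genes, so their counts do not belong to 1 gene. Next came Inpp4b (52), Sox5 and Pde4d (51 each), Gm37240, whose model encloses 6 other genes, and Maml2 (50 each), Lpp (45), Wwox (43) and Hivep3 (42). Maml2, which encodes a Notch coactivator, held 11.6 regions per 100 kb, the highest rate of these 10, and Pde4d the lowest at 3.35.

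The 1000 strongest regions were more often promoters than shared regions in general, but the very top was mostly distal. The 10th distal region had a mean signal rank of 11 and the 10th promoter region one of 80.75. Of the 1000 with the best mean signal rank 27.5% were at promoters, against 19.8% of all shared regions; ranked by -log10 q the share was 72.6%. The 10 strongest distal regions lay nearest to Cntnap5b, Limd1, Gphn, Gm8797, Myl12b, Arhgef26, 4930467E23Rik, Zfp945, Neto1 and Col19a1. The strongest region lay 407501 bp from the Cntnap5b TSS on chromosome 1, with a signal of 37.9 ± 0.863 (SD, n = 4). The 10 strongest promoter regions were nearest to the histone genes Hist1h4m and Hist1h4n, 2310009B15Rik, Cacng2, Tnfrsf23, 5430403G16Rik, Dynlt1a, Rbm12b1, Gm49359 and Mrpl44. Hist1h4m led with a signal of 33.2 ± 0.896.

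The last comparison asked which transcription factor motifs lay at region summits. At distal summits the AP-1 string, bound by BATF, JUN and FOS proteins, was present in 20.2% ± 0.150 (SD, n = 4) of summits and 2.22% ± 0.041 of flanks, a ratio of 9.11 ± 0.233 against 2.15 ± 0.044 for the reversed string. The AP-1/IRF composite bound by BATF with IRF4 had a ratio of 11.6 ± 1.09 (reversed 2.55 ± 0.368), with a match at 0.340% ± 0.012 of summits. This string contains the AP-1 string, so its ratio is not separate from that of AP-1. CTCF, the insulator protein, had the highest ratio, 26.5 ± 0.699 (reversed 0.658 ± 0.123), with a match at 3.51% ± 0.142 of summits. NF-kB followed at 2.5 ± 0.060, RUNX at 2.12 ± 0.043 and ETS at 1.92 ± 0.057. The ROR string, bound by nuclear receptors of that family, had a ratio of 1.40 ± 0.045, little above its reversed string at 1.29 ± 0.058. STAT had 1.40 ± 0.133 (reversed 0.759 ± 0.020), and its values went with the library tag: 1.51 and 1.52 in replicates 1 and 2 and 1.27 and 1.30 in replicates 3 and 4. Other ratios at distal summits, among them those of AP-1, ETS and PU.1/IRF, also split by tag. Those of CTCF, RUNX, NF-kB, NFAT, GATA, T-box, NFY, KLF/SP and the AP-1/IRF composite did not, and some such splits arise by chance. With 2 replicates per tag no exact test of such a difference can pass 0.05.

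At distal summits NRF1 had a ratio of 2.07 ± 0.294, with a match at only 0.024% of summits, and KLF/SP 1.43 ± 0.030 (reversed 1.31 ± 0.036). Below 1 were GATA at 0.623 ± 0.006, TCF/LEF at 0.949 ± 0.004, NFY at 0.874 ± 0.006 and the liver control HNF4 at 0.654 ± 0.113. The PU.1/IRF control of myeloid and B cells had 1.91 ± 0.064 (reversed 0.898 ± 0.053). At promoter summits this control had 1.60 ± 0.142 (reversed 0.589 ± 0.111). It passed the counting rule at both, so the counts of strings below include a control. At promoter summits the order differed, with CTCF at 6.44 ± 0.461, NRF1 at 3.50 ± 0.213, AP-1 at 3.28 ± 0.194, ETS at 2.74 ± 0.031 and NFY at 2.33 ± 0.026. The KLF/SP string had 2.05 ± 0.053 there and its reversed string 1.99 ± 0.054. In all, 12 of 19 strings at distal summits and 7 of 19 at promoter summits had a lowest ratio above 1 and above the highest reversed ratio. KLF/SP at promoter summits was above its reversed string within each replicate. It was not counted because its lowest ratio (1.97) was below the highest reversed ratio (2.06). NRF1 was not counted because its reversed string had no match in the flanks of replicate 4. In a window of 25 bp the CTCF ratio at distal summits was 1.05, and in a window of 100 bp the AP-1 ratio was 5.93. Of CTCF matches within 100 bp of a distal summit, 0.824% ± 0.174 (SD, n = 4) were centred within 15 bp of it, and of AP-1 matches 23.7% ± 0.330.

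**Figure D3:**
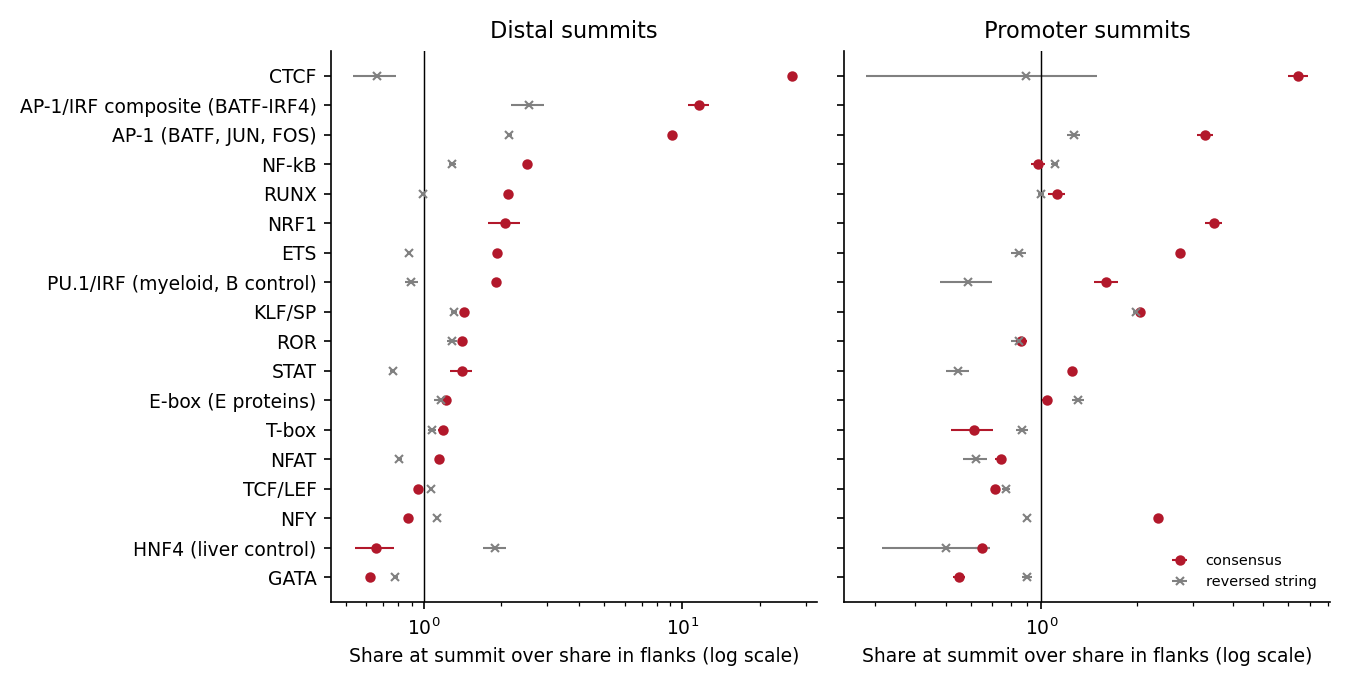
Share of summits with each consensus over its share in the flanks (log scale) at distal and promoter summits, with red circles for the consensus and grey crosses for the reversed string; bars are 1 SD over 4 replicates. At distal summits CTCF (26.5), the AP-1/IRF composite (11.6), which contains the AP-1 string, and AP-1 (9.11) stand highest, and GATA (0.623) lowest.

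**Figure D4:**
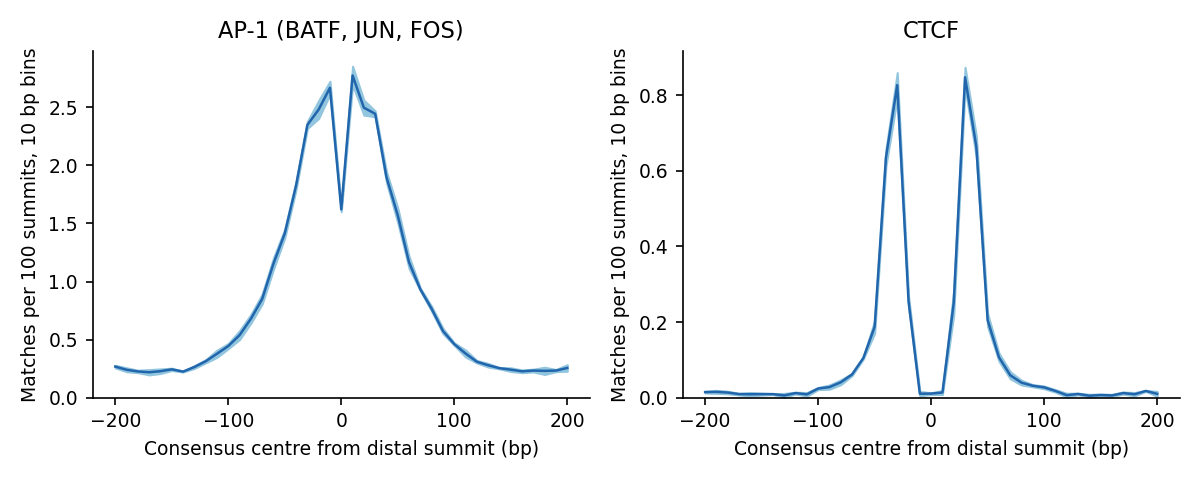
Matches of the AP-1 and CTCF strings per 100 distal summits in bins of 10 bp, by distance of the match's centre from the summit in bp; lines are means and bands 1 SD over 4 replicates. CTCF matches peak 30 bp to either side of the summit and are nearly absent within 15 bp (0.824% of those within 100 bp).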

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

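All tests in this part were chosen before their results were seen. Chance sets 1 replicate apart in about 1 in 20 groups of 4, and 3 of 69 quantities checked had a replicate far from the others. Region density in the B cell list was 2.21 in replicate 4 and from 2.31 to 2.32 in the others. The ROR ratio at distal summits was 1.47 in replicate 4 and from 1.37 to 1.38 in the others. The KLF/SP ratio at distal summits was 1.39 in replicate 2 and 1.45 in each of the others. Outside the compared chromosomes, a mean of 82.25 regions per replicate (75 to 87) lay on unplaced sequences or the mitochondrial genome, 2 of them in each replicate on the mitochondrial genome; there are no control samples to set beside them.

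Replicates with the same tag in their peak names were more alike than others, with mean Jaccard indices of 0.777 and 0.761. Lists of unequal length are argued against: within the strongest 50000 regions of each replicate the gap between tags was 1.34 times that in the full lists, where this explanation needed a ratio under 0.5. Widths also went with the tag (medians of 624 and 619 bp against 661 and 654), but with every region set to 401 bp about its summit the gap kept 0.964 of its value, where under 0.5 was needed. Regions present in both replicates of 1 tag and neither of the other numbered 3943, against 2400 and 2406 for the other splits into pairs, a ratio of 1.64 to the higher. This is consistent with a difference between the tags in preparation, culture or cells, but with 3 such splits in all a share under 0.05 cannot be reached. Which of these the tags stand for is open, and no biological explanation was tested, since the labels give 1 group.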

How the results depend on the processing

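The counts from distal regions only and the promoter reading from merged shared regions were chosen after the result was seen; the other alternatives were planned. No paired analysis was possible because there is only 1 group. Of the main results of the comparisons, 113 alternative values kept their direction and side of the threshold or stayed within the spread, 24 moved and 5 passed a threshold that they had missed. Of the single lists, genes and motifs, 624 stayed, 80 moved, 21 came to pass, 15 no longer passed and 1 reversed. Except where a value below gives it, the cause was not tested.

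The share of merged regions counted as shared moved under every alternative, from 54.5% with summits within 100 bp to 85.1% with regions in at least 2 replicates (72.3% to 72.8% leaving out each replicate).

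A -log10 q of at least 5 gave a Jaccard index of 0.784, a promoter fold of 7.69 and an AP-1 ratio of 9.98, and at least 10 gave 0.797, 8.52 and 10.6. With at least 10, lists with higher promoter openness numbered 8 instead of 6, with Th2 and polarising cytokine input gained, the neuron list passed as less open (-27.2) and hepatocyte as less dense. The strongest 50000 regions of each replicate gave 43295 shared regions, by construction fewer, a Jaccard index of 0.791, a promoter fold of 9.97, an AP-1 ratio of 11 and 2 lists with higher promoter openness instead of 6. There the naive or memory list fell below its random lists, by -11.7 points (adjusted permutation p = 0.722; range over its alternatives 0.0042 to 0.722), the neuron (-40.2) and epithelium (-35.3) lists passed as less open, and shared regions at Il17a numbered 2 instead of 5. The promoter fold was 12.3 with a window of 500 bp and 5.92 from 2 kb upstream to 500 bp downstream. AP-1 ratios were 9.75 in a window of 25 bp, 5.93 in 100 bp and 11 with flanks 400 bp away. Promoters made up 24.4% of the 500 strongest regions, 36.0% of the 5000 strongest and 72.6% of the top ranked by -log10 q.

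Th17 density exceeded Th2 density by 0.63 with regions in at least 3 replicates, 0.60 in at least 2 and 0.76 without matching, each raising the count of called helper differences from 0 to 1. Leaving out each replicate gave 0.52 to 0.57 and a count of 0 to 1. Without matching, the openness calls of the Treg and naive or memory lists and the density calls of the Th2 and housekeeping lists ended; activation, polarising cytokine input and housekeeping passed as more open, B cell, myeloid and hepatocyte as less open, and hepatocyte as less dense. With a promoter window of 500 bp polarising cytokine input passed as more open and neuron as less open. The naive or memory openness call also ended with regions in at least 3 replicates, and it and the muscle call with the window from 2 kb upstream. Depth is unknown, so how far it limits the lists was not tested.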

Other observations

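The test of crowding and both tests of where the CTCF string lies were chosen only after the result was seen. The housekeeping test on distal regions only was added after seeing the data but before its own result, and the other tests in this part were chosen before theirs. Naive and memory T-cell genes, which are background to an effector programme, included the 2 genes with the most shared regions in any list. These were Foxp1, with 68 over 597384 bp, and Bach2, with 59 over 347305 bp. Lef1 had 22 over 113886 bp. Such counts of single genes are not adjusted for gene length. All 12 polarising cytokine input genes had open promoters, with 19 shared regions at the interleukin 6 receptor gene Il6ra and 18 at Smad3, a mediator of TGF-beta signalling. Among activation genes Nfkb1 had 22 and Jun 1. Cd247, the T-cell receptor zeta chain gene, had 20. Ebf1, a B cell regulator, had 20 over 390775 bp and an open promoter, although Cd79a, Pax5 and Blk of the same list were not open in all 4 replicates. Of 6 Y-linked genes examined, Uty and Eif2s3y had open promoters in 4 replicates, Ddx3y in 3, Kdm5d in 1 and Zfy1 and Sry in 0.

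Repeat sequence made up 13.9% ± 0.224 (SD, n = 4) of the bases in listed regions against 36.4% of the genome. The genome share counts all known bases, and the peak names carry a word for masked reads. How far reads from repeats were kept is unknown, so whether repeats are scarce in open chromatin was not tested.

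The distal regions with the best mean signal rank were looked at as a set, and the Il2ra locus held many regions of very low rank, down to a percentile of 0.032 ± 0.018 (SD, n = 4). Of the strongest 100 distal regions, 1 matched the mitochondrial genome and 6 had a near-identical copy elsewhere (0 and 1 of 100 random distal regions), and 4 held the CTCF string (5 of 100 random ones), so none of these makes up most of the set. Shared distal regions with at least 3 others within 10 kb ranked lower in signal than isolated ones by -23.6 ± 0.712 percentile points (31.9 against 55.5), though by 1.47 ± 0.286 points higher in -log10 q. The signal value may therefore be lower where open regions lie close together, which would place isolated regions at the top: 57 of the strongest 100 had no neighbour, against 27.2% of all distal regions. In groups of like width the difference ranged from -26.2 to -15.9, short of the 20 points asked of every group, so this stays open, and no biological explanation was tested.

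The CTCF ratio at distal summits was 26.5 within 50 bp but 1.05 within 25 bp. Of CTCF centres within 100 bp of a summit, 0.824% ± 0.174 (SD, n = 4) lay within 15 bp of it, against 15.4% if evenly spread, and the profile peaked 30 bp to either side. Of the longer AP-1/IRF composites 14.2% ± 1.21 lay within 15 bp. A count of centres asks for no fit of the string inside the narrow window. It therefore cannot test whether a long string fits there less often. The flank windows had the same size, however, so a poorer fit would lower both shares and not by itself their ratio. This argues against string length alone as the reason for the fall to 1.05. An earlier test of string length, on composite ratios in a 25 bp window, came within its spread of the bound and was replaced by the count of centres. Why summits lie beside the string was not tested.

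Other hypotheses were tested. Housekeeping genes may exceed length-matched genes through promoters of neighbours: with distal regions only their excess was 0.43 instead of 0.75 and no longer passed (adjusted permutation p = 0.0714; range over its alternatives 4.5e-04 to 0.159), but it did not fall below the 50% set in advance, so this stays open. Whether Th17 loci hold stronger rather than more regions stays open: the best region per gene averaged percentile 68.5 in 15 Th17 genes and 71.5 in 54 other helper genes, a difference of -2.97 (permutation p = 0.606), and signal ranks were lower where regions lie close together. AP-1 matches rose with signal: 28.1% ± 0.506 of the strongest 25% of distal regions held one and 12.3% ± 0.273 of the weakest 25%, a ratio of 2.29 ± 0.053 (SD, n = 4). For CTCF the ratio was 1.30 ± 0.150, between the bounds set for either outcome. ROR matches lay in 4.62% of 130 shared distal regions at Th17 loci (6) and in 2.17% of 230 at other helper loci (5). Regions are not independent replicates, and 54 of the 130 lie at Rora, so whether ROR matches are concentrated at Th17 loci stays open.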
